A study of Mus musculus with 12 samples.

How the data were processed

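Gene expression was measured by RNA sequencing of bilateral striatum from male C57BL/6J mice that had drunk ethanol after saline or varenicline. Of the 12 libraries, 6 carried the saline label and 6 the varenicline label. Per the labels' protocols, Illumina TruSeq RNA libraries were read as single reads of 150 nt. Whether strand was recorded and whether each library came from a single mouse is not given in the sources used here, so the p-values measure the spread between these samples. Replicate numbers follow the order of deposition and pair nothing.

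The main values were the deposited gene counts, whole numbers that were not normalized, 1 column per library. Per the submitters' processing notes, Trimmomatic, FastQC, TopHat2, featureCounts, DESeq2, Cuffdiff and Cuffnorm were used with the build mm10; versions and annotation are not given in the sources used here. The authors also deposited FPKM values and, in another table, a signal of scaled counts per gene, by its file name from Cuffnorm; both were used only as alternatives. Gene length was the exon length given per the file headers. The count table held 24421 genes, none on the mitochondrial chromosome. Of its 23401 Ensembl identifiers, 23230 were found in GENCODE vM21, and 99.4% of those overlapped the same gene there. The 27 symbols turned into dates by a spreadsheet were restored through their identifiers, and positions below are those of the count table.

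Genes with enough counts (filterByExpr of edgeR 4.0.16, by group) numbered 15148. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test at the package's default settings, varenicline against saline, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are log2, varenicline minus saline, with standard errors from the fit. A total of 34 gene lists were written down before the data were examined, together with the tests, the rule for naming genes and most of the alternatives. Lists with at least 4 tested genes, 31 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. For the 15 cell type lists, a score per library was the mean log2 CPM of the list's genes with a prior count of 2, compared by a two-sided exact permutation test over all 924 assignments.

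The genes named are every tested receptor subunit that varenicline can bind; where fewer than 24 genes passed, the 8 per direction with the smallest unadjusted p, leaving out predicted genes; and, in the lists described, up to 4 members with the smallest p, of which not all are given. Up to 15 per direction would have been named had genes passed. A few genes named outside this rule are said to have been chosen after their values were seen.

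The alternatives were other size factors, other filters, DESeq2 1.42.0, limma-voom with sample weights, robust dispersion, limma on log2 of FPKM plus 1 or 0.1 and on log2 of the Cuffnorm values plus 1, up to 3 surrogate variables from sva 3.50.0, scores of cortical, choroid plexus or oligodendrocyte markers as covariates, removal of each library's gene length trend, and each library left out. Alternatives added after seeing the data were edgeR's newer dispersion option, DESeq2 with the cortical score, cortical and septal scores together, the cortical score without the library varenicline 6, and DESeq2 without that library. R was 4.3.3, and figures were drawn with matplotlib 3.10.9.

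The tests were tried on simulated data with 200 changed genes among 15148. The changed genes were drawn only from well-counted ones, and every gene was simulated independently, without the variation that genes share in the real libraries. In that setting edgeR recovered 42% of the genes changed 1.25-fold, 88% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. It made 14 false calls, and 0 calls when no gene was changed. DESeq2 recovered 52%, 92%, 96% and 100% with 33 false calls, and made 2 calls when no gene was changed. Its false calls thus outnumbered those of edgeR, 33 against 14, so calls of DESeq2 and edgeR were not equally strict there. In the real counts DESeq2 gave no adjusted p for 11926 genes, so its adjustment did not run over the same genes as that of edgeR. Library totals ran from 13340420 to 27917715 counts. At those depths, 3 counts corresponded to between 0.107 and 0.225 CPM, a floor that covers counting error only. All 66 pairs of libraries differed by more than sampling noise, with a lowest chi-square per degree of freedom of 6.48. Ethanol intake per animal was not analysed here.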

Results

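Striatal RNA was profiled in 12 libraries from male C57BL/6J mice, an inbred strain that drinks ethanol readily. Of these, 6 came from animals injected with saline and 6 from animals given varenicline at 2 mg/kg. Varenicline is a smoking cessation drug that acts as a partial agonist at nicotinic acetylcholine receptors built from alpha4 and beta2 subunits. The mice drank 20% ethanol in a limited-access test, Drinking-in-the-Dark, in which a session of 2 h started 3 h after lights off. There were 3 cycles of 2 days, and the assigned injection came 30 min ahead of drinking in 2 of them. The comparison asked which striatal transcripts differ between drug and vehicle in drinking mice. Library totals averaged 23324001 ± 5011872 counts with saline and 19584990 ± 4307321 with varenicline (SD, n = 6 each; exact permutation p = 0.190).

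Differences between the groups were spread over many genes, and some were large, with log2 fold changes of -1.23 for Slc17a7 and 1.32 for Zic4. Markers of cortical excitatory neurons were lower in the varenicline libraries, while markers of septum and pallidum, oligodendrocytes, astrocytes and striatal projection neurons, and genes induced by glucocorticoids, were higher as lists. With an estimated correlation none of these lists passed (camera adjusted p from 0.465 to 0.629), and the shared projection neuron list was lower with the cortical score as a covariate. Among single genes, Tfcp2l1, Pdk4, Clk1, Rgs2 and Cdc42ep3 were the highest ranked on the upper side, and Dok5 and Ehbp1 on the lower side. None of the 15148 genes tested passed an adjusted p of 0.05 in edgeR, 0 higher and 0 lower. At an unadjusted p under 0.05 there were 1100 higher and 1458 lower genes, against 379 per direction by chance. DESeq2 called 387 genes, 139 higher and 248 lower, and limma-voom with sample weights called 2099. In the simulated data DESeq2 made more false calls than edgeR, so these numbers do not rest on equally strict calls. Without varenicline 6, whose cortical score lay in the saline range, edgeR called 1628 genes, 541 higher and 1087 lower, but with the cortical score as a covariate on the same libraries it called 0, with 1779 at an unadjusted p under 0.05. DESeq2 with that covariate called 26 genes in all 12 libraries, 8 of them among its 387. Members of the immediate early list among the 26 included Junb, Egr2, Cyr61 and Arc, picked out after their values were seen. With that covariate edgeR called 9 genes in all 12 libraries, 7 of them in the immediate early list. Of that list it called 0 once varenicline 6 was left out. The groups did not overlap at all for 115 genes, 0.759% of those tested, where chance gives 0.216%.

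The 16 genes with the smallest p, none past the threshold in edgeR, had all 6 varenicline libraries on the same side of the saline mean. Selection by p favours such a pattern. Tfcp2l1 (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168 on mm10), a transcription factor of the grainyhead family, averaged 9.44 ± 1.04 CPM with saline and 14.9 ± 1.74 CPM with varenicline (SD, n = 6). Its log2 fold change was 0.65 (SE 0.096, edgeR adjusted p = 0.0679). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496278), a kinase that restrains the pyruvate dehydrogenase complex, had a log2 fold change of 0.38 (SE 0.062) and the same edgeR adjusted p. Clk1 (ENSMUSG00000026034, chromosome 1, 58411988 to 58424088), a kinase of splicing factors, averaged 140 CPM with saline and 187 CPM with varenicline. The log2 fold changes were 0.41 for Clk1, 0.46 for Rgs2, a regulator of G protein signalling, and 0.37 for Cdc42ep3. Tiparp had 0.53, Vcl, which encodes the adhesion protein vinculin, 0.27, and Slc26a5 0.85. On the lower side, Dok5 (ENSMUSG00000027560, chromosome 2, 170731807 to 170879775), an adaptor of receptor tyrosine kinases, averaged 20.0 ± 0.652 CPM with saline and 14.3 ± 1.77 CPM with varenicline. Its log2 fold change was -0.48 (SE 0.079, edgeR adjusted p = 0.0679). The values were -0.29 for Ehbp1, -0.25 for Large, which glycosylates dystroglycan, -0.60 for Mas1, a receptor for angiotensin 1-7, and -0.27 for Anxa7. Tuba4a, a tubulin, had -0.26, Usp13 -0.36 and Ptk2, the focal adhesion kinase, -0.24. DESeq2 called 15 of the 16 at its adjusted p of 0.05, all but Slc26a5. With the cortical score as a covariate it called 4, namely Tfcp2l1, Clk1, Rgs2 and Tiparp. The genes were picked by p from these same counts, so the DESeq2 calls are not independent support. Counts of Vcl, Mas1, Tuba4a and Large could include reads of genes on the opposite strand, since the use of strand is not given. The same limit holds for Chrnb2, Zic4, Nrn1, Sult1a1, Gad1 and Fkbp5, whose values are given below.

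**Figure D1:**
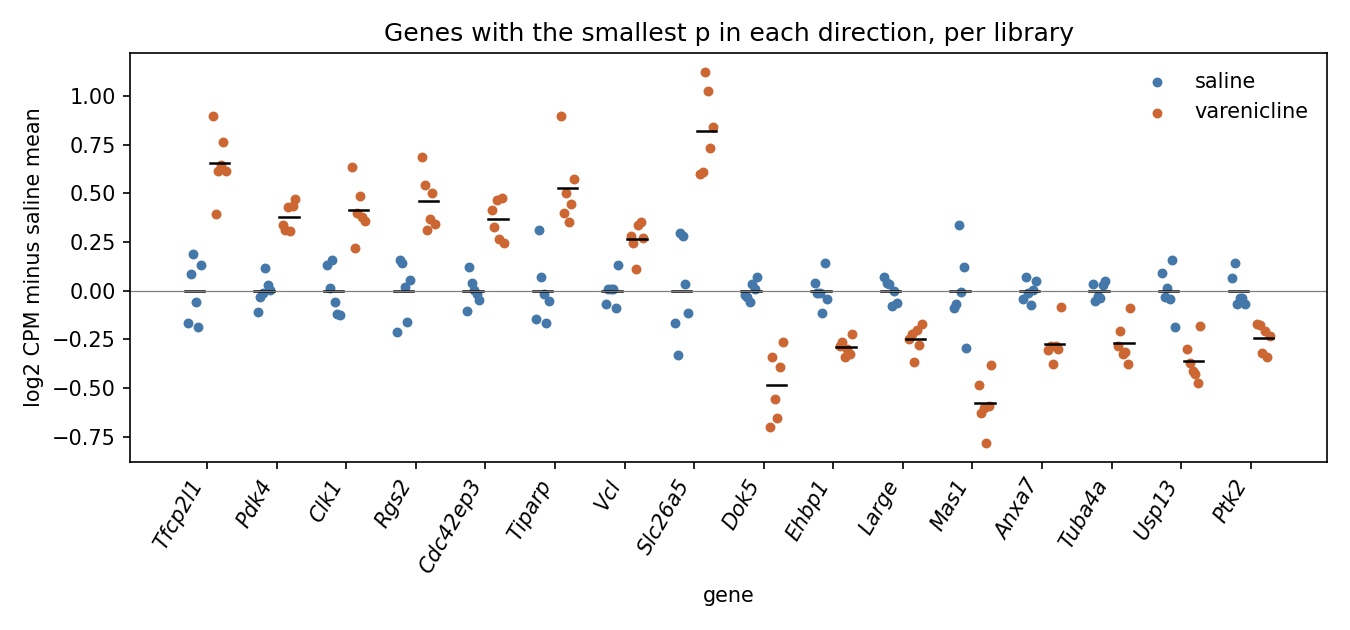
Log2 CPM minus the saline mean for the 16 genes with the smallest p, 1 point per library and a bar at each group mean (n = 6 each). Every varenicline point lies on 1 side of the saline mean for each gene, and the ranges of the groups are apart for 14 of the 16. The genes were picked by p, which favours both.

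Among the receptors varenicline can bind, the alpha4 subunit transcript had the smallest p. Chrna4 (ENSMUSG00000027577, chromosome 2, 181022311 to 181039177) averaged 40.3 ± 8.29 CPM with saline and 26.0 ± 4.80 CPM with varenicline (SD, n = 6). Its log2 fold change of -0.63 (SE 0.137) had an edgeR adjusted p of 0.132 over all genes and of 0.00249 adjusted over the list alone, where it was the single gene of 8 to pass. DESeq2 gave Chrna4 an adjusted p of 0.00376, and with the cortical score as a covariate its log2 fold change was -0.38 (SE 0.155, edgeR adjusted p = 0.946). Without varenicline 6 the edgeR adjusted p was 0.00227. Over all alternatives, those with DESeq2 and limma included, the adjusted p ran from 1.4e-06 to 0.996. All 6 varenicline libraries were below the saline mean. Chrnb2, the partner subunit, differed by -0.11 (66.6 and 61.8 CPM), and by -0.0641 without varenicline 5. Chrna7 differed by 0.02, a sign that turned in several alternatives. Among scarcer subunits, the log2 fold changes were 0.62 for Chrna3, -0.59 for Chrna5, -0.46 for Chrnb3, -0.42 for Chrnb4 and -0.08 for Htr3a, none past the threshold; the signs of Chrna5, Chrnb3, Chrnb4 and Htr3a turned when the cortical score was taken into account in some fits. Leaving out each library, Chrnb3 ran from -0.85 without varenicline 6 to -0.15 without varenicline 3, and Chrnb4 from -0.63 without varenicline 2 to -0.17 without varenicline 3. As a list these genes did not pass (camera adjusted p = 0.116), except with the filter of at least 1 CPM in 6 libraries (adjusted p = 0.0401, range 0.0401 to 0.997 over the alternatives), and they passed fry's test of either direction (adjusted p = 0.0496). That filter leaves out scarce subunits such as Chrnb3, which averaged 0.525 CPM with saline and 0.406 CPM with varenicline, so a smaller list was tested there. Chrna2, Chrna6 and Htr3b had 45, 30 and 7 counts over all 12 libraries and were too low to test.

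**Figure D2:**
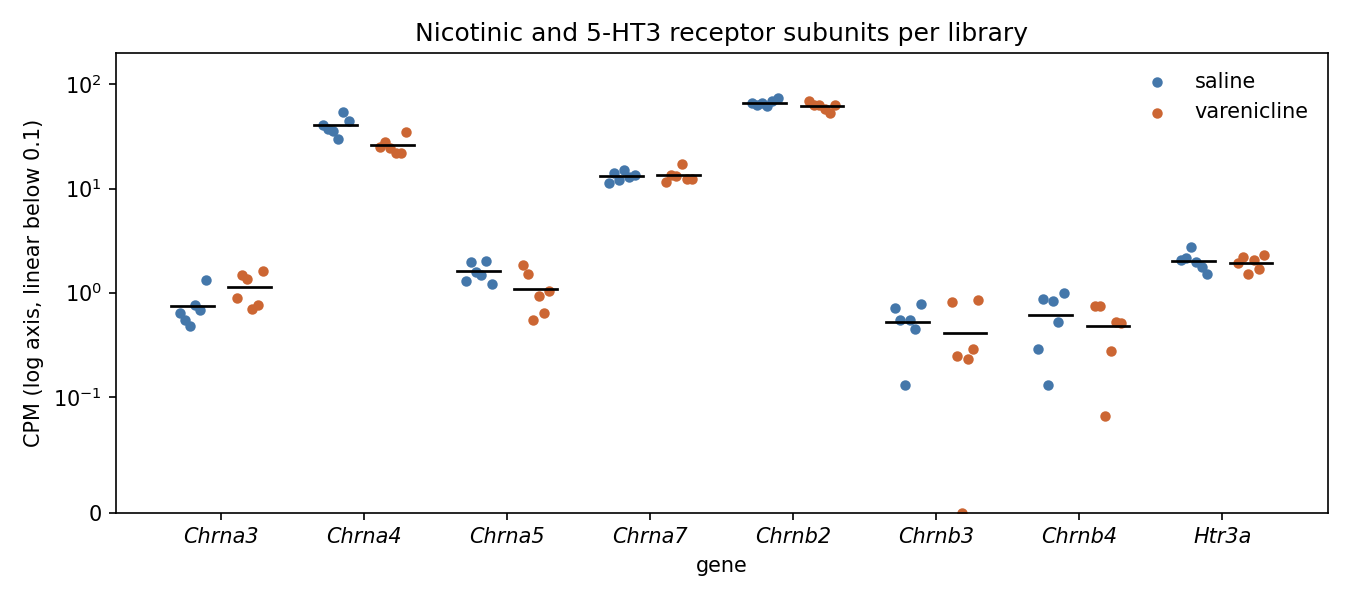
CPM of 8 nicotinic and 5-HT3 receptor subunit genes on a log axis that is linear below 0.1, 1 point per library with bars at group means (n = 6 each). Chrna4 averaged 40.3 CPM with saline and 26.0 CPM with varenicline, while Chrna7 averaged 13.2 and 13.3 CPM.

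Of the 31 lists tested, 9 passed an adjusted p of 0.05 in camera with a preset correlation, 8 higher and 1 lower. None passed with an estimated correlation or in fry's test of 1 direction, and 10 passed fry's test of change in either direction. The cortical excitatory list fell (camera adjusted p = 1.2e-07, but adjusted p = 0.545 with an estimated correlation), with 13 of 14 genes lower, 9 of them at an unadjusted p under 0.05, 0 past the threshold over all genes and 8 past it adjusted over the list alone. Nrn1 had a log2 fold change of -1.30, Tbr1 -1.21 and Slc17a7, the cortical vesicular glutamate transporter, -1.23, from 590 to 251 CPM. Of the 14 genes 1 is also in another list, and all 14 had enough counts to be tested in this tissue. The cortical score was 5.13 ± 0.311 with saline and 4.12 ± 0.792 with varenicline in log2 CPM (SD, n = 6; exact permutation p = 0.0173, adjusted p = 0.130 over 15 scores). In varenicline 6 it was 5.40, inside the saline range of 4.75 to 5.52. None of the 15 score differences passed after adjustment, and without varenicline 6, 4 did.

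Septal and pallidal markers rose as a list (camera adjusted p = 1.2e-04, adjusted p = 0.465 with an estimated correlation), with 9 of 12 genes higher at an unadjusted p under 0.05, 4 of them adjusted over the list alone. Over the alternatives the camera adjusted p ran from 9.6e-06 to 0.763, and 30 of 32 passed the list. The log2 fold changes of its transcription factors Zic4 and Zic5 were 1.32 and 1.48, and that of Dlk1 was 1.19. Without varenicline 1 that of Zic4 was 0.87, and without varenicline 3 that of Dlk1 was 0.74. Its score was 2.84 ± 0.143 with saline and 3.34 ± 0.439 with varenicline (exact permutation p = 0.00866, adjusted p = 0.130). It was highest in varenicline 1 and 3, at 3.90 and 3.91, and lay between 3.01 and 3.18 in the other 4, against a highest saline value of 3.06. All 14 shared projection neuron markers were higher, 3 at an unadjusted p under 0.05 (camera adjusted p = 7.3e-05, adjusted p = 0.629 with an estimated correlation), with 0.26 for Arpp21 and 0.27 for Rgs9. With the cortical score as a covariate this list was lower instead (camera adjusted p = 0.00204), and its adjusted p ran from 4.5e-09 to 0.995 over the alternatives. Rgs9 and Arpp21 then had the opposite sign. The direct pathway list rose (camera adjusted p = 0.00125, adjusted p = 0.629 with an estimated correlation), with 0.24 for Pdyn, 0.38 for Tac1 and 0.32 for the dopamine receptor gene Drd1. Its camera adjusted p was 0.8096 with the cortical score as a covariate, in the lower direction, as was the sign of Drd1, and over the alternatives it ran from 2.2e-05 to 0.971. The indirect pathway list did not pass (camera adjusted p = 0.336, range 0.0156 to 0.705 over the alternatives, past the threshold in the higher direction with limma-voom and in the lower direction in 2 fits with the cortical score), with 6 of 7 genes higher and the remaining gene lower adjusted over the list alone.

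**Figure D3:**
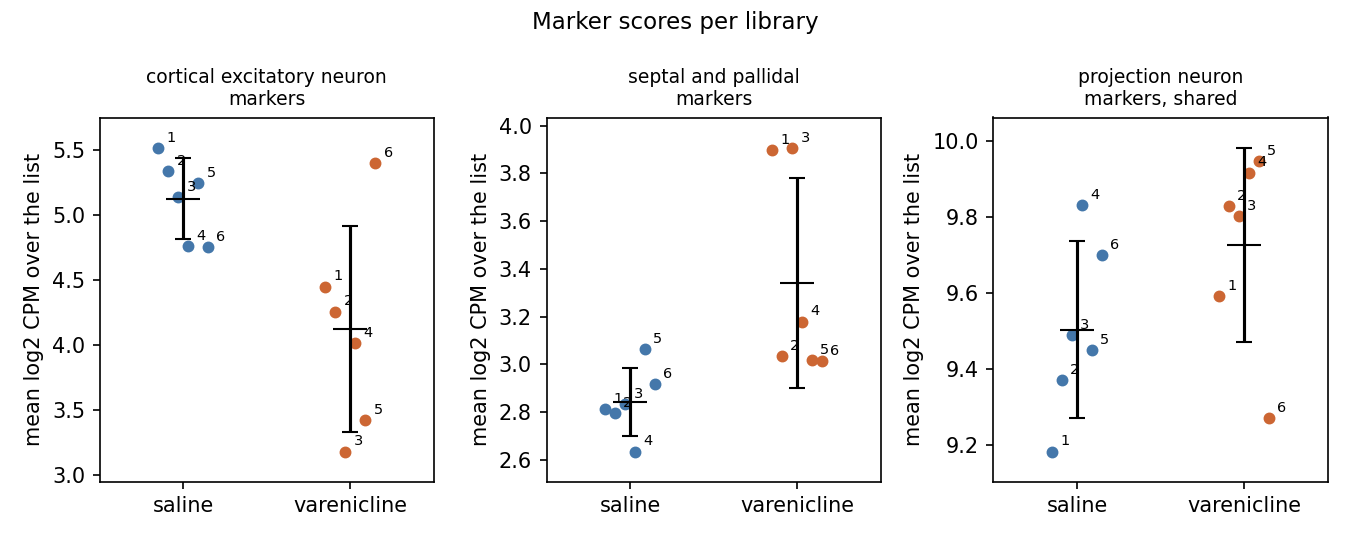
Mean log2 CPM over 3 marker lists per library, with replicate numbers, group means and SD bars (n = 6 each). The cortical score averaged 5.13 with saline and 4.12 with varenicline, with varenicline 6 at 5.40, and the shared projection neuron score averaged 9.50 and 9.73.

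The oligodendrocyte list rose (camera adjusted p = 3.6e-05, adjusted p = 0.629 with an estimated correlation), with 15 of 16 genes higher, among them Hapln2 at 0.32 and the myelin claudin Cldn11 at 0.26. Its camera adjusted p was 0.8096 with the cortical score as a covariate, and over the alternatives it ran from 4.5e-09 to 0.995. The astrocyte list rose (camera adjusted p = 0.0104, adjusted p = 0.629 with an estimated correlation), with 13 of 14 genes higher and with 0.21 for the bicarbonate transporter gene Slc4a4 and 0.19 for Gja1, which encodes a gap junction protein. Without varenicline 6 the camera adjusted p of the astrocyte list was 0.0973, and over the alternatives it ran from 2.4e-06 to 0.893. The astrocyte list passed in 29 of 32 of them. Microglia markers, 8 of 14 higher, and oligodendrocyte precursor markers, 6 of 11 higher, did not pass (camera adjusted p = 0.5996 and 0.854); the microglia list passed in 1 of 32 alternatives (range 0.00540 to 0.995). Ependymal markers, all 11 higher and none at an unadjusted p under 0.05, passed with an adjusted p of 0.0496 in camera and 0.723 with an estimated correlation. That call was lost in 7 of the 12 fits that left out a library: saline 1, 3, 4 and 5 and varenicline 1, 3 and 4, with adjusted p up to 0.422.

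Genes induced by stress hormone rose as a list (camera adjusted p = 3.6e-05, adjusted p = 0.465 with an estimated correlation). Of its 19 tested genes 15 were higher, 7 at an unadjusted p under 0.05 and 6 adjusted over the list alone. Besides Pdk4 they included the metallothionein gene Mt2 (log2 fold change 0.34), Sult1a1 (0.67) and Fkbp5, a chaperone partner of the glucocorticoid receptor (0.29, from 46.1 to 56.7 CPM). The immediate early list passed with an adjusted p of 0.0330 in camera and had 0.7501 with an estimated correlation. Without a covariate its members went both ways, 7 higher and 3 lower at an edgeR unadjusted p under 0.05. Egr2 averaged 5.19 and 12.1 CPM and the log2 fold change of Cyr61 was 0.79, whereas that of Nr4a2 was -1.25. Without varenicline 6 that of Cyr61 was 0.49. With the cortical score as a covariate 19 members were higher and 0 lower at that unadjusted threshold. With that covariate and without varenicline 6 these numbers were 11 and 0. The camera call of the list was lost in 6 of the 12 fits that left out a library, without saline 1, 3, 4 or 5 or varenicline 1 or 6. Without varenicline 6 the camera adjusted p of that list was 0.856, and over all alternatives with the preset correlation it ran from 1.3e-42 to 0.856.

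The cholinergic, dopamine, neuropeptide, glutamate and GABA lists did not pass in camera in the main edgeR fit. The dopamine list passed with DESeq2 (camera adjusted p = 0.0330) and 7 other alternatives, and the cholinergic list with limma-voom alone (camera adjusted p = 0.0301), with ranges from 0.0129 to 0.972 and from 0.0301 to 0.987. In fry's test of change in either direction, the cholinergic, GABA, glutamate and neuropeptide lists passed (adjusted p from 0.0425 to 0.0496). Among cholinergic genes, the muscarinic receptor genes Chrm3 and Chrm2 had log2 fold changes of -0.69 and -0.40, and the choline transporter gene Slc5a7 had 0.38; these 3 passed adjusted over the list alone. The signs of Chrm3 and Chrm2 turned with the cortical score as a covariate and without varenicline 6. Among dopamine genes Slc18a2, the vesicular monoamine transporter, had 1.81, from 0.555 ± 0.243 to 2.01 ± 2.00 CPM (SD, n = 6 each), and Ddc had 0.34. Leaving out each library, the log2 fold change of the scarce Slc18a2 ran from 1.23 to 2.01. Among neuropeptides 3 were higher and 4 lower adjusted over the list alone, and 1 of the 3, Pomc, was at -0.19 without varenicline 6. Pdyn had 0.24 and Tac1 0.38, and Sst had -0.32, Cck -1.07 and Cartpt -0.91. In the GABA list Gabbr2 had -0.74, Gabra3 -0.63 and Gad1 0.21. Over all alternatives, those with DESeq2, limma and the cortical score included, the adjusted p of these genes depended on the fit. It ran from 4.3e-13 to 0.996 for Gabbr2, from 2.4e-04 to 0.999 for Gabra3 and from 6.7e-04 to 0.999 for Gad1. For Cck and Sst it ran from 6.5e-05 to 0.999 and from 2.0e-06 to 0.999.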

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

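The random covariates, the fit with the cortical score and without varenicline 6, the spreads set beside each bound and, for the glucocorticoid list, the ratios of medians and the exact test of its score were chosen after related results had been seen. Of 154 sets of 6 values examined, 11 held a library far from the other 5, where chance gives 7.7 at 1 in 20. Of these 11, 6 concerned varenicline 6. In log2 CPM that library had the highest value of the varenicline group for Anxa7 (6.21, others 5.91 to 6.01) and the lowest for Cldn11 (7.86), Hapln2 (5.65) and Pdyn (6.31). Its direct pathway score of 5.36 was also the lowest of its group, where the other 5 lay between 5.74 and 5.93. Its value for Pomc, a gene singled out after its values were seen, was 4.80, or 487 counts, where the other varenicline libraries lay between -0.52 and 0.19. Single values stood apart for Chrna7 in varenicline 4 (4.11), Chrnb3 in saline 3 (-2.17), Mt2 in varenicline 2 (5.94) and Per2 in varenicline 3 (6.16). The oligodendrocyte score of saline 6 was 7.996, above the others of its group at 7.75 to 7.82.

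More genes reached an unadjusted p under 0.05 in edgeR than chance gives, 2558 against 757. Among 100 splits drawn from 462, 1, the real one, gave as many genes, and the highest other split gave 2209. Chance is thus a less likely cause of that number but is not excluded. The real split also had the largest cortical score difference of the 100. At adjusted p 0.05 it called 0 genes in edgeR, while 3 other splits called some, up to 12. A trend with gene length cannot be the cause, because the number was 2615 once it was removed. The fold changes of the 16 named genes then kept 1.04 times their median size. An unequal share of cortex stays open. Over the splits, which are not independent, the number of genes followed the difference in cortical score (rho = 0.567). The covariate left 782 genes, under the bound of 1136. With it the 16 fold changes kept 0.855 of their median size (bootstrap SE 0.119, bound 0.75). That bootstrap resampled genes, not libraries, so its SE does not measure the spread between libraries. Without varenicline 6 the covariate took the number from 3980 to 1779, also a fall but not to the bound. With all libraries, 3 of 40 random covariates as correlated with treatment as the cortical score (r = -0.675) left as few as 782. An unequal share of cortex therefore cannot be told apart from an effect of varenicline. Ethanol intake was not analysed here, so a difference in it could not be told apart from that effect either.

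Cortical markers were lower in the varenicline libraries, and the first principal component, with 29.4% of the variance, followed the cortical score (absolute r = 0.975, permutation p = 1e-05, the smallest possible; rho = 0.972, permutation p = 1e-05; r = 0.965 without the 2 farthest libraries). A candidate explanation is an unequal share of cortex in the dissected tissue, for which fold changes should follow the slope on the score inside saline libraries. Across genes, which are not independent replicates, that rho was 0.124 (jackknife SE 0.174, bound 0.2), which leaves the question open. With the slope taken inside the varenicline libraries, where the drug was given, rho was 0.502. The slopes of the saline and varenicline libraries had rho = 0.213 with each other. No bound had been set for these values. For the other explanation, lower expression in the same cells, unrelated cortical and projection neuron scores inside the groups had been predicted. Their deviations from the group means had r = -0.823 (jackknife SE 0.172, permutation p = 7.3e-04), not beyond its spread from the bound of -0.7. The rank correlation was rho = -0.839 (permutation p = 0.00192), and r was -0.910 without the 2 farthest libraries. These values go with a share of cortex that varies between samples. Such a share would give a negative r inside the groups whether or not varenicline lowers these genes. Inside the saline libraries alone r was -0.976. The test therefore cannot decide between the explanations of the group difference.

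The glucocorticoid list stayed past the threshold of camera in all 12 fits that left out a library, with adjusted p from 1e-07 to 4.5e-04, and in all 32 alternatives with the preset correlation, up to 0.0397. Its median log2 fold change with the cortical score as a covariate was 0.973 of that without it (bootstrap SE 1.12). With astrocyte and oligodendrocyte scores it was 1.28 of that without them (bootstrap SE 1.29). Both spreads were too wide to exclude a part for either. They came from resampling the list's genes, not libraries, and do not measure the spread between libraries. Chance can not be excluded: the exact permutation p of its score was 0.0281, and 0.201 adjusted over the 31 lists. The number of lists past the threshold says little by itself, since 46 of 100 splits gave as many as the real 9, up to 14. A stress hormone difference between the groups may therefore be named as a hypothesis, which hormone levels in such mice would test.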

How the results depend on the processing

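Alternatives named here with DESeq2 and the cortical score, with cortical and septal scores, or without varenicline 6 beside another change were chosen after seeing the data. No paired analysis was possible because every library carries the same replicate number in the labels, so the numbers used here pair nothing. Other size factors, filters, robust or newer dispersion, FPKM, Cuffnorm values, the choroid plexus score and the length trend left the counts at adjusted p 0.05 at 0. Genes higher and lower at adjusted p 0.05 numbered 139 and 248 with DESeq2, 730 and 1369 with limma-voom, 14 and 1 with surrogate variables, 9 and 0 with the cortical score, 1 and 0 with the oligodendrocyte score, 25 and 1 with DESeq2 and the cortical score, and 775 and 1383 with DESeq2 without varenicline 6. Leaving out each library gave 0 to 541 higher and 0 to 1087 lower, the upper ends without varenicline 6; without varenicline 2 there were 4 higher. Genes higher and lower at unadjusted p 0.05 numbered 1968 and 2371 with limma-voom, 581 and 559 with surrogate variables, 470 and 312 with the cortical score, 625 and 650 with the oligodendrocyte score, 520 and 341 with DESeq2 and the cortical score, 367 and 349 with cortical and septal scores, and 1850 and 2245 with DESeq2 without varenicline 6. With the cortical score and without varenicline 6, 835 were lower. Leaving out each library gave 768 to 1911 higher genes. The higher share of these genes was 43.0%, 50.1% with the length trend removed and 60.1% with the cortical score. Lists past the threshold numbered 0 with an estimated correlation and 0 in fry's test of 1 direction, where its test of either direction gave 10, and 6 to 13 in the others. Score differences past it numbered 0 to 4 when each library was left out, 4 without varenicline 6. Log2 fold changes turned sign as follows. With surrogate variables Chrna7 was at -0.0463, Chrnb3 0.40, Htr3a 0.0424, Drd1 -0.0646, Arpp21 -0.0178 and Tac1 -0.0275. With the cortical score Chrna7 was at -0.0604, Chrnb3 0.38, Htr3a 0.19, Drd1 -0.0832, Arpp21 -0.0481 and Rgs9 -0.0318; with DESeq2 and that score they were at -0.0569, 0.41, 0.20, -0.0801, -0.0447 and -0.0288. With the cortical score and without varenicline 6 Chrna5 was at 0.67, Chrna7 -0.0413, Chrnb3 0.34, Chrnb4 0.0215, Htr3a 0.34, Chrm3 0.0212, Chrm2 0.0621, Bdnf 5.9e-04, Rgs9 -0.0918, Tbr1 0.18, Slc17a7 0.0655 and Pomc -0.13. With cortical and septal scores Chrnb3 was at 0.34, Chrnb4 0.0674, Htr3a 0.27 and Bdnf 0.00327. With the oligodendrocyte score Chrna7 was at -0.0421 and Htr3a 0.10. Chrna7 was at -0.00319 with Cuffnorm values, and Pomc at -0.22 with DESeq2 without varenicline 6. Leaving out each library, Chrna7 ran from -0.0615 to 0.0680, Htr3a from -0.15 to 0.0405 and Pomc from -0.19 to 2.77. The cause of these changes was not tested. Chrna2, Chrna6 and Htr3b had too few counts for a test at this depth.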

Other observations

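The exact test of the immediate early score, the fit with the cortical score and without varenicline 6, and the values of Egr2 per library were chosen after related results had been seen. The clock list was not past the threshold (camera adjusted p = 0.0887), with 12 of 18 genes higher. Its log2 fold changes included 0.42 for Per1 and 0.34 for Per2, which are both also induced by glucocorticoids and by neuronal activity. With the cortical score as a covariate the camera adjusted p of the list was 1.5e-04, and over all alternatives with the preset correlation it ran from 6.2e-07 to 0.260. Among neurotrophin genes Gdnf had a log2 fold change of 0.46, and Bdnf, much of which is made in cortex, had -1.05. The 22 lists that did not pass had camera adjusted p values from 0.0590 to 0.975. The lowest belonged to the dopamine list and to the unfolded protein response, of which 13 of 15 genes were lower; these passed in 8 and 10 of 32 alternatives, with adjusted p from 0.0129 to 0.972 and from 6.4e-04 to 0.971. Nuclear respiratory chain genes had 24 of 29 lower (camera adjusted p = 0.0624, past the threshold in 8 alternatives, range 0.0200 to 0.310) and the highest value belonged to the neuroimmune list, with 7 of 15 genes higher. The ethanol metabolism list had 7 of 12 genes higher (camera adjusted p = 0.5996). The median and the mean of a list's fold changes, or the direction of camera, differed in sign for the neuropeptide, GABA and glycine, endothelial and oligodendrocyte precursor lists, none of which passed. No mitochondrially encoded gene was in the count table, and the hypothalamic and red blood cell lists had 3 and 2 tested genes, too few for a test.

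Choroid plexus scores ran from 0.645 to 4.30 log2 CPM over the 12 libraries, with 2.03 ± 1.51 for saline and 2.46 ± 1.57 for varenicline (SD, n = 6 each; exact permutation p = 0.647). Leaving out each library moved the difference of 0.43 to between 0.0588 without varenicline 5 and 0.84 without saline 2. All 13 genes were higher (camera adjusted p = 0.230), and the list passed in 4 of 32 alternatives, among them those without saline 2, saline 5 or varenicline 3 (range 1.5e-04 to 0.995).

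The immediate early score was 4.12 ± 0.111 with saline and 4.25 ± 0.490 with varenicline (SD, n = 6 each; exact permutation p = 0.556). It was 5.005 in varenicline 6 and 4.65 in varenicline 1, against a highest saline value of 4.28 and a lowest varenicline value of 3.67. Of its 31 genes, 7 were higher at an unadjusted p under 0.05 in edgeR without a covariate, 19 with the cortical score as a covariate and 11 with that covariate and without varenicline 6. The numbers of lower genes in these fits were 3, 0 and 0. Egr2 was at 22.8 CPM in varenicline 1 and 17.1 CPM in varenicline 6, and at most 6.69 CPM in a saline library.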
